A study of Mus musculus with 6 samples.

How the data were processed

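RNA abundance was measured in 6 libraries of endothelial cells sorted by flow cytometry from the lungs of wild-type mice, 3 libraries from mice aged 18 months (labelled aged) and 3 from mice aged 8 months (labelled mAdu). Per the labels' protocols, RNA was isolated from frozen cell pellets with a kit for very small samples (PicoPure), 10 ng of total RNA went into each library with the SMARTer Ultra Low kit, and reads of 100 bp were taken from both ends on the HiSeq platform. The markers used for the sort are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be in part technical.

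The deposited values are TPM, a measure of transcript abundance relative to the sum over all transcripts of a library, for 24520 Ensembl gene identifiers, 1 column per library. Per the submitters' processing notes, kallisto, a program that assigns reads to transcripts without a full alignment, and the genome build mm10 were used. The version of kallisto, the transcript set, the way transcripts were summed to genes and any strand setting are not given in the sources used here. The values sum to between 869315 and 876126 TPM per library, so part of the total lies outside the table, which has no mitochondrially encoded and no ribosomal RNA gene. TPM keep no read depth, so the depth of each library is unknown and no counting error is given. Between 17325 and 17513 genes per library lay above 0. kallisto shares out reads between near-identical transcripts, so values of recent gene copies and of genes with processed pseudogenes, such as those of ribosomal proteins, are uncertain. The kit does not mark the strand, so genes that overlap on opposite strands share reads.

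Gene symbols, biotypes, positions, lengths and GC content were taken from GENCODE release M21 on GRCm38, the assembly called mm10, in which 24299 of the identifiers were found and 221 were not. All computations used R 4.3.3 and limma 3.58.1. Values were tested as log2(TPM + 1) for the 12748 genes with a mean of at least 1 TPM over the 6 libraries. Log2 differences are on that scale, which understates the change of genes with low values. The comparison of 18 with 8 months used limma's moderated test with an intensity trend, 2-sided, age as the sole term and Benjamini-Hochberg adjustment, with 0.05 as the threshold. Intervals are at the 95% level.

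Of 43 gene lists, written with the design and the named-gene rule before the data were examined, 39 had at least 5 tested genes and were tested with limma's camera, which compares the genes of a list with the rest, at a preset inter-gene correlation of 0.01 and with adjustment over the 39 lists. The lists held 912 distinct genes, of which 735 were tested. Members were also adjusted over the list alone. Genes were named if they were among the 12 largest rises or 12 largest falls past the threshold, with groups that did not overlap and a mean of at least 5 TPM in the higher group. Predicted genes and genes without a symbol were to be counted, not named. Where fewer passed, up to 6 next genes per direction by unadjusted p are given as values that did not pass. The 6 DNA methylation and demethylation enzymes were named whatever their result, as were up to 4 members of each list with the smallest unadjusted p. One predicted gene, Gm7609, is named outside this rule and was chosen after its values were seen. So were the neighbouring genes given beside the genes that passed, and Cd74, Ednrb, Emp2, Gbp2, H2-K1, Lyz2, Nlrc5, Pcna, Prox1, Reln, Sftpc, Sparc, Xist and Ddx3y, which are list members outside the 4 with the smallest unadjusted p.

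The gene test and the list test were tested on simulated data for the 12748 genes with the means and variances of these libraries. In groups of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale, the limma test called 9, 35, 50 and 50. It also called 12 genes that had not been changed, and with no gene changed it called 0 genes and 0 lists. The simulated genes varied independently of each other, which real genes do not. The changed genes were all changed in the same simulated set and all had a mean of at least 5 TPM. Many true changes ease the adjusted threshold, so these shares are likely too high for a comparison with few calls.

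Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, rescaling each library to the same sum, limma without the trend, library weights, the replicate number as a block, each library left out in turn, and, for the lists, an estimated inter-gene correlation and limma's fry. After the data were seen, 4 more were added, namely a correction for GC content and transcript length (a loess trend with a span of 0.75 per library, fitted on genes with a mean of at least 5 TPM), that correction with the block, protein-coding genes alone, and removal of the 1195 small RNA genes with rescaling. Exon overlap and shared 31-base sequences of Gm7609 were computed from the same annotation, also after the data were seen, and the transcript set used upstream may differ from it.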

Results

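Endothelial cells, which line the blood and lymph vessels, were sorted from the lungs of wild-type mice aged 18 months (3 libraries) and 8 months (3 libraries), and their RNA was sequenced. The series concerns DNA methylation that depends on DNMT3A and the enhancers of endothelial cells, and the 6 libraries address what differs in the transcriptome between the 2 ages. The values are TPM from kallisto. Their depth is unknown. Across the 12748 tested genes the libraries correlated at 0.974 to 0.982 within an age and at 0.966 to 0.977 across ages, in log2(TPM + 1). These correlations are across genes, which are not independent replicates. Xist, transcribed from the inactive X chromosome, lay at 36.2 ± 10.6 TPM (SD, n = 3) at 18 months and 34.8 ± 5.03 TPM at 8 months, and the Y-linked Ddx3y at 0.138 and 0.213 TPM.

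At 18 months, genes that present antigen on MHC class II were higher, with H2-Ab1 at 1240.5 ± 473.5 TPM (SD, n = 3) against 468.7 ± 62.5 TPM at 8 months, and cell cycle genes were higher. Markers of monocytes, macrophages and dendritic cells had a median log2 difference of 0.55 over the 11 tested of 20 listed genes. None of them passed adjusted over the list alone, and their per-library means overlapped between the ages, with the third 8-month library highest. Markers of aerocytes, a capillary cell type of the alveolus, were lower, with Ednrb at 496.0 ± 76.2 TPM against 843.4 ± 168.3 TPM, as were markers of veins. These are calls on gene lists that were lost with an estimated inter-gene correlation (smallest adjusted p = 0.50). At the level of single genes 3 passed.

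The DNA methyltransferases did not pass the test. Dnmt3a, which sets new methylation marks, lay at 11.2 ± 1.81 TPM (SD, n = 3) at 18 months and 13.5 ± 1.59 TPM at 8 months, a log2 difference of -0.26 with a 95% interval from -0.63 to 0.10 (limma adjusted p = 0.53). Its libraries overlapped, at 12.8, 9.21 and 11.5 TPM at 18 months and 12.2, 15.3 and 13.1 TPM at 8 months. Dnmt1, which copies marks after replication, lay at 40.2 ± 7.36 and 43.5 ± 1.14 TPM, and Dnmt3b at 7.11 ± 0.348 and 6.63 ± 0.665 TPM. The TET enzymes, which oxidise methylated cytosine, did not pass either. Tet1 lay at 3.65 ± 0.695 and 3.95 ± 0.919 TPM, Tet2 at 4.91 ± 1.99 and 7.17 ± 3.91 TPM, and Tet3 at 10.1 ± 3.31 and 12.3 ± 1.01 TPM, each at 18 and then 8 months. Dnmt1 and Tet1 went the other way without the second 18-month library, with log2 differences of 0.019 and 0.032. So did Tet1 without the second 8-month library, at 0.013, and Dnmt1 with the correction for GC content and length, at 0.074. Of the 19 tested genes of the DNA methylation machinery, 0 passed over all genes tested and 0 adjusted over the list alone. The list as a whole had a median log2 difference of -0.12, a mean of -0.063 and a camera direction of higher relative to the other genes (adjusted p = 0.64), so the median and the test differ in sign. The median was 0.019 without the second 18-month library, -0.029 without the third 8-month library, -0.032 with median-of-ratios scaling, -0.020 with quantile normalization and 0.014 with the correction for GC content and length. Uhrf1, which brings DNMT1 to replicated DNA, had the smallest unadjusted p in this list, with 3.03 ± 1.25 TPM at 18 months and 1.32 ± 0.284 TPM at 8 months.

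Of the 12748 genes, 1 rose and 2 fell between 8 and 18 months. Gm7609, a transcribed pseudogene on chromosome 1 (85199613 to 85213786, GRCm38), rose 5.93-fold, from 2.46 ± 0.149 TPM at 8 months to 14.6 ± 3.30 TPM at 18 months (SD, n = 3), a log2 difference of 2.15 with an SE of 0.18 (limma adjusted p = 0.034). It lies inside the span of C130026I21Rik on the opposite strand (84992690 to 85270566), which lay at 1.41 TPM at 8 months and 3.94 TPM at 18 months. The annotated exons of this pair shared 0 bases and their transcripts 0 sequences of 31 bases. Of the 31-base sequences in Gm7609 transcripts, 48.3% also occurred in transcripts of other genes, 27.3% in those of Gm15433 and 11.4% in those of Sp100, so its value is uncertain. Lmbr1 on chromosome 5 (29229802 to 29378390), a membrane protein gene whose intron holds a limb enhancer of Shh, was 3.36-fold lower at 18 months, with 3.65 ± 0.439 TPM against 12.3 ± 1.18 TPM, a log2 difference of -1.51 with an SE of 0.15 (limma adjusted p = 0.048). Frrs1 on chromosome 3 (116859464 to 116908177), which encodes a ferric-chelate reductase, was 2.51-fold lower, with 26.6 ± 3.49 TPM against 66.9 ± 6.64 TPM, a log2 difference of -1.30 with an SE of 0.13 (limma adjusted p = 0.048). In each of these 3 genes all 18-month libraries lay on one side of all 8-month libraries.

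The next genes by unadjusted p did not pass. On the higher side, Fam183b lay at 6.88 ± 0.594 TPM at 18 months against 1.87 ± 0.239 TPM at 8 months. Top2a, the topoisomerase of dividing cells, lay at 5.20 ± 1.39 against 0.792 ± 0.326 TPM, and Pimreg at 6.22 ± 2.08 against 0.617 ± 0.412 TPM. The microRNA gene Mir7663 lay at 7.72 ± 1.21 against 2.21 ± 0.621 TPM. Its annotated span (chromosome 10, 22729372 to 22729432) is shorter than a read of 100 bp, so what its value measures is uncertain. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, lay at 11.1 ± 6.89 against 0.494 ± 0.622 TPM, and Rps19 at 474.2 ± 73.3 against 256.2 ± 12.6 TPM. Their limma adjusted p lay between 0.062 and 0.079. On the lower side, Carmil1 lay at 6.82 ± 0.912 against 16.0 ± 0.660 TPM and Rbms3 at 2.16 ± 0.350 against 6.65 ± 0.466 TPM. Bcam, a laminin receptor, lay at 152.3 ± 29.5 against 323.5 ± 32.5 TPM and Lypla2 at 28.7 ± 3.92 against 55.3 ± 5.67 TPM. Fndc1 lay at 7.81 ± 2.03 against 19.6 ± 1.32 TPM and Rprml at 9.75 ± 3.37 against 26.6 ± 0.795 TPM. The limma adjusted p of these 6 lay between 0.077 and 0.091. At an adjusted p under 0.1 there were 17 higher and 13 lower genes. At an unadjusted p under 0.05 there were 440 higher and 1274 lower genes, where chance alone gives 637. The groups did not overlap in 2383 genes, 18.7% of those tested, where chance gives 10%. The split depended on the scaling: with median-of-ratios scaling 2 genes passed as higher and 1 as lower, and 741 higher stood against 894 lower at the unadjusted threshold. Quantile normalization gave 9 and 7 past the adjusted threshold and 751 and 979 at the unadjusted one. With the correction for GC content and length the majority turned, with 815 higher against 720 lower at the unadjusted threshold, and 763 against 663 with the replicate block added.

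None of the 3 calls held when any 1 library was left out, where limma gave 0 to 2 genes in all and the adjusted p of the 3 genes lay between 0.051 and 0.190. Over all alternatives their log2 differences stayed between 1.98 and 2.50 for Gm7609, between -1.72 and -1.43 for Lmbr1 and between -1.38 and -1.19 for Frrs1. Frrs1 did not pass with median-of-ratios scaling, limma without the trend, a pseudocount of 0.1 or the correction for GC content and length. The number of genes was 0 with no filter on low values (2203 at an unadjusted p under 0.05), 94 with library weights, 28 among protein-coding genes alone, 25 with small RNA genes removed and 3 with a correction for GC content and length, where 2 were higher and 1 lower.

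**Figure D1:**
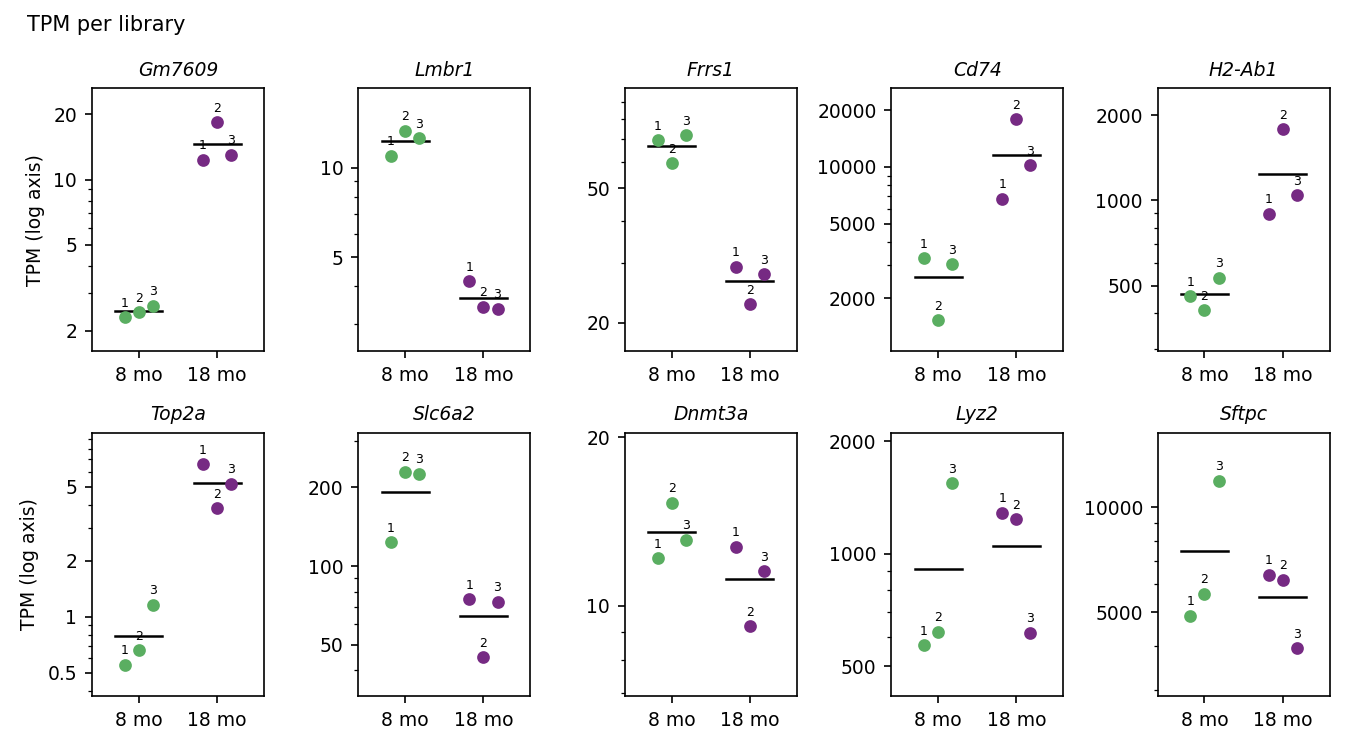
TPM on log axes in each library for 10 genes, with 8-month libraries in green, 18-month libraries in purple, small digits giving the replicate number and bars giving group means. Frrs1 lies between 22.7 and 29.3 TPM at 18 months and between 59.4 and 71.9 TPM at 8 months, while Lyz2 and Sftpc are highest in the third 8-month library.

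Of the 39 gene lists, 7 rose and 5 fell by camera with the preset correlation, and 27 did not pass. Of the 10 ways to split the 6 libraries into 3 and 3, 5 gave at least 12 list calls, the ages included, and the highest other split gave 15. So the number of list calls does not set the ages apart from other splits, a comparison chosen after the results were seen. None of the 12 calls held with an estimated inter-gene correlation, where the smallest adjusted p was 0.50, and fry, which asks whether a list moves one way on balance, called 0 lists. A second fry test asks whether members change in either direction. Its adjusted p was under 0.05 for the cell cycle, aerocyte, MHC class II, endothelial-mesenchymal, fibroblast and smooth muscle lists. It was not for the other called lists, such as MHC class I (0.11) and interferon (0.20). Some lists that camera did not call passed it, such as imprinted genes (0.0032). Over all genes tested, 0 members of any list passed, and the counts of members below are those adjusted over the list alone. Of the 730 distinct genes in these lists, 77 passed in that way, 30 higher and 47 lower. In mean log2(TPM + 0.1) per library the ages did not overlap in 13 of all 39 lists, where chance gives 10% for a single list. Some lists share genes and all share the libraries, so they are not independent. Of the 13, 7 were among the 12 called lists, which were picked on the same libraries, and 6 were not. Among the called lists the ages overlapped in the interferon, general capillary, venous, airway and macrophage lists.

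MHC class II presentation, the machinery that displays extracellular peptides to CD4 T cells, rose at 18 months with a median log2 difference of 1.28 (camera adjusted p = 2.5e-12, adjusted p = 0.50 with an estimated correlation). Of its 10 tested genes, 9 were higher, and 8 passed adjusted over the list alone. The invariant chain gene Cd74 lay at 6762, 17910 and 10253 TPM in the 18-month libraries and at 3259, 1533 and 3027 TPM in the 8-month libraries. H2-Ab1 lay at 1240.5 ± 473.5 TPM at 18 months against 468.7 ± 62.5 TPM at 8 months (SD, n = 3), H2-Eb1 at 735.9 ± 305.2 against 244.1 ± 50.0 TPM, H2-DMa at 354.0 ± 198.1 against 79.1 ± 17.2 TPM and H2-DMb1 at 405.1 ± 125.6 against 169.3 ± 9.33 TPM. Markers of monocytes, macrophages and dendritic cells moved the same way, with a median log2 difference of 0.55 over 11 genes (camera adjusted p = 0.00017, adjusted p = 0.78 with an estimated correlation). In mean log2(TPM + 0.1) these markers lay at 3.76 in the third 8-month library, above the 18-month libraries at 3.13 to 3.67 and the other 8-month libraries at 1.997 and 2.31. Of these markers 0 passed adjusted over the list alone. Chil3 lay at 260.0 ± 125.4 against 66.1 ± 64.1 TPM, Cd68 at 28.9 ± 7.42 against 17.6 ± 9.95 TPM and Lyz2 at 1287, 1235 and 614.3 TPM against 568.0, 618.8 and 1542 TPM. The median of the marker list was 1.08 without the third 8-month library and 0.35, 0.20 and 0.25 without the first 18-month, the first 8-month and the second 8-month library. It was 0.22 with no filter, 0.33 when each library was rescaled to the same sum, and 0.35 with library weights. The marker call was lost without the second 8-month library (camera adjusted p = 0.101) and without the second 18-month library (camera adjusted p = 0.052).

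MHC class I presentation rose with a median log2 difference of 0.43 over 16 genes (camera adjusted p = 4.9e-08, adjusted p = 0.50 with an estimated correlation), and 6 of them passed as higher adjusted over the list alone. H2-Q4 lay at 218.8 ± 47.7 against 141.1 ± 8.76 TPM, H2-K1 at 2956.5 ± 436.8 against 2190.1 ± 120.3 TPM and Nlrc5, the transactivator of class I genes, at 34.9 ± 10.1 against 20.3 ± 3.58 TPM, at 18 and 8 months (SD, n = 3). Values of the class I genes are uncertain where near-identical copies share reads. The interferon response list rose with a median log2 difference of 0.17 over 31 genes (camera adjusted p = 9.8e-09, adjusted p = 0.65 with an estimated correlation). Of its genes 26 were higher, and 1 passed adjusted over the list alone, Oas2, a sensor of double-stranded RNA, with 42.0 ± 2.34 against 22.2 ± 4.12 TPM. Zbp1 lay at 37.7 ± 15.5 against 17.4 ± 2.42 TPM and Gbp2 at 302.5 ± 143.3 against 169.2 ± 11.6 TPM. The second 18-month library had the highest values of Zbp1, Gbp2 and Cd74, and without it the medians were 0.063 for the interferon list, 0.25 for MHC class I and 1.02 for MHC class II. The interferon median was 0.11 without the second 8-month library, 0.27 with median-of-ratios scaling and 0.27 with the correction for GC content and length.

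Cell cycle genes rose with a median log2 difference of 0.37 over 26 genes (camera adjusted p = 2.8e-14, adjusted p = 0.50 with an estimated correlation). Of these, 21 were higher and 9 passed adjusted over the list alone. The monocyte, macrophage and dendritic cell markers rose alongside, by 0.76 with an SE of 0.57 in mean log2(TPM + 0.1) per library against 0.85 with an SE of 0.16 for the cell cycle list. Kif20a, a kinesin of cell division, lay at 4.32 ± 0.732 TPM at 18 months against 1.10 ± 0.173 TPM at 8 months (SD, n = 3), cyclin Ccnb2 at 4.96 ± 1.08 against 0.915 ± 0.425 TPM and cyclin Ccnb1 at 2.46 ± 0.593 against 0.271 ± 0.158 TPM. The replication gene Pcna lay at 114.1, 114.3 and 126.1 TPM at 18 months and at 108.2, 100.0 and 110.3 TPM at 8 months. Among the 12 cell cycle genes with a mean of at least 5 TPM the median was 0.067 (camera adjusted p = 0.013). Without the first 18-month library, 24 genes of the list had a mean of at least 1 TPM, and their median was 0.23.

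Among the vessel types, markers of aerocytes, the large capillary cells of the alveolus, fell with a median log2 difference of -0.63 (camera adjusted p = 2.0e-09, adjusted p = 0.50 with an estimated correlation). All 14 of their tested genes were lower, and 12 passed adjusted over the list alone. The endothelin receptor gene Ednrb lay at 496.0 ± 76.2 TPM at 18 months against 843.4 ± 168.3 TPM at 8 months (SD, n = 3), Emp2 at 570.1 ± 47.3 against 854.6 ± 93.0 TPM, the transcription factor Tbx3 at 139.3 ± 21.2 against 217.2 ± 5.08 TPM, Tbx2 at 10.2 ± 0.721 against 18.4 ± 3.52 TPM and the peptide hormone gene Apln at 45.9 ± 6.69 against 70.0 ± 4.49 TPM. Venous markers fell with a median of -0.77 (camera adjusted p = 0.0015, adjusted p = 0.78 with an estimated correlation), with 11 of 11 genes lower and 3 past the threshold adjusted over the list alone. These were the noradrenaline transporter gene Slc6a2 at 64.3 ± 16.8 against 192.9 ± 59.9 TPM, Cpe at 3.36 ± 1.34 against 14.9 ± 6.54 TPM and Nr2f2, the transcription factor of venous identity, at 6.34 ± 0.486 against 12.6 ± 3.90 TPM. In mean log2(TPM + 0.1) the venous list lay at 4.33 in the first 8-month library, within the 18-month range of 3.96 to 4.47, and at 5.64 and 5.31 in the other 8-month libraries. The venous median was -0.40 without the second 8-month library. With the correction for GC content and length the falls shrank, to medians of -0.45 for aerocytes and -0.67 for veins. Both lists still passed by camera, and the median of all genes moved by 0.092. Markers of general capillaries rose with a median of 0.12 over 10 genes (camera adjusted p = 0.015, adjusted p = 0.78 with an estimated correlation), and 0 passed adjusted over the list alone. Of these, 8 were higher and 2 lower. Sema3c lay at 538.9 ± 37.8 against 399.2 ± 48.2 TPM, Cd93 at 511.8 ± 38.9 against 414.2 ± 37.9 TPM and Cxcl12 at 214.0 ± 48.1 against 163.3 ± 37.6 TPM. Plvap, with the largest change in the list, was lower, at 152.1 ± 26.4 against 285.4 ± 137 TPM. The general capillary call was lost with quantile normalization (camera adjusted p = 0.066) and without the third 18-month, the first 8-month or the third 8-month library, with medians of 0.066, 0.052 and 0.053. The median was 0.077 without the first 18-month and 0.24 without the second 8-month library, 0.22 with median-of-ratios scaling, 0.20 with library weights and 0.23 with the correction for GC content and length.

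The genes of endothelial-mesenchymal transition fell with a median log2 difference of -0.28 (camera adjusted p = 0.0025, adjusted p = 0.51 with an estimated correlation). Of 14 genes 13 were lower and 3 passed adjusted over the list alone, namely Col1a1 at 0.390 ± 0.238 TPM against 1.79 ± 0.415 TPM, Ccn2, a matricellular growth factor, at 25.3 ± 10.6 against 74.2 ± 34.1 TPM and Tagln, an actin-binding protein of smooth muscle, at 4.71 ± 0.558 against 7.93 ± 1.71 TPM (SD, n = 3). Markers of mesenchymal cells, with which this list shares Col1a1 and Tagln, moved with it. The smooth muscle and pericyte markers fell with a median of -0.67 over 10 genes (camera adjusted p = 1.5e-05, adjusted p = 0.50 with an estimated correlation), 6 of which passed adjusted over the list alone, Myh11 at 2.16 ± 0.455 against 4.12 ± 0.293 TPM and Pdgfrb at 2.58 ± 0.560 against 5.21 ± 1.52 TPM among them. Its median was -0.43 with no filter. The fibroblast and mesothelium markers fell with a median of -0.51 over 11 genes (camera adjusted p = 0.0012, adjusted p = 0.50 with an estimated correlation), 2 of which passed adjusted over the list alone, Col1a1 and Dcn, with Dcn at 4.13 ± 0.241 against 11.98 ± 5.84 TPM. The fibroblast call was lost without the first 8-month library (camera adjusted p = 0.056), and its median was -0.90 with a pseudocount of 0.1. With the correction for GC content and length the falls shrank here too. The medians were then -0.21 for the endothelial-mesenchymal list, -0.53 for smooth muscle and pericytes and -0.38 for fibroblasts and mesothelium. Each list still passed by camera.

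The airway epithelium markers rose with a median log2 difference of 0.55 over 8 genes (camera adjusted p = 0.0015, adjusted p = 0.50 with an estimated correlation), and 0 passed adjusted over the list alone. The club cell secretoglobin gene Scgb1a1 lay at 9171 ± 3608 TPM against 6312 ± 928.9 TPM and Cyp2f2 at 363.3 ± 124.5 against 188.5 ± 45.9 TPM (SD, n = 3). The median was 0.28 without the first 18-month library, 0.34 without the first 8-month library, 0.18 with library weights and 0.31 with no filter. Markers of other cells that did not pass were those of the alveolar epithelium (camera adjusted p = 0.48), T and NK cells (0.20), B and plasma cells (0.49) and erythroid cells and platelets (0.97). In mean log2(TPM + 0.1) these 4 lists and the macrophage list were highest in the third 8-month library, with T and NK cells at 2.68 against 0.749 to 2.20 in the other libraries. The surfactant gene Sftpc lay at 11881 TPM in it and at 3945 to 6399 TPM in the other libraries, the B cell gene Cd79a at 11.4 TPM against 2.66 to 4.63 TPM, and the haemoglobin gene Hba-a1 at 634.9 TPM against 115.6 to 255.8 TPM. Without that library 13 lists passed, 8 as higher and 5 as lower.

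**Figure D2:**
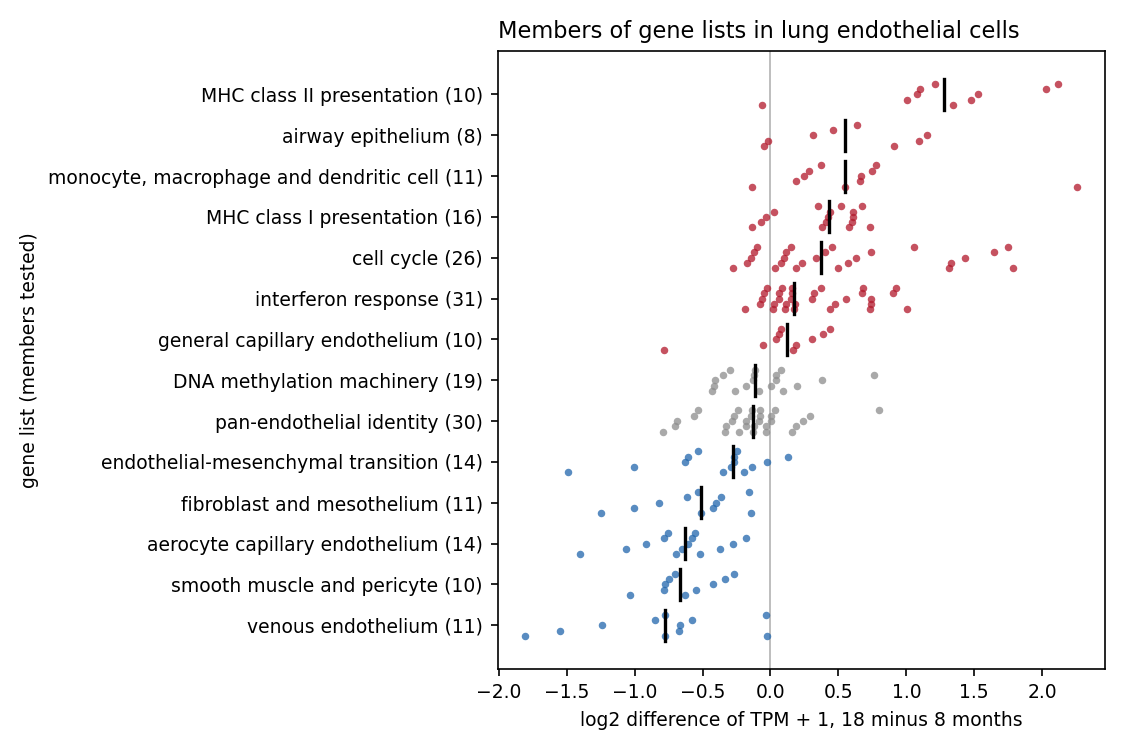
Log2 difference of TPM + 1 between 18 and 8 months for each tested member (dots) of the 12 gene lists past the camera threshold and 2 that were not, with list medians as black bars and the number of tested members in brackets. Red lists rose, blue lists fell and grey lists did not pass, and all 14 aerocyte genes lie left of 0.

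Lists of endothelial function did not pass by camera. Pan-endothelial identity had a median log2 difference of -0.13 over 30 genes (adjusted p = 0.39), with 1 gene higher and 2 lower past the threshold adjusted over the list alone. These were Ecscr at 530.9 ± 42.5 TPM at 18 months against 305.6 ± 33.6 TPM at 8 months, the VEGF receptor gene Kdr at 372.8 ± 36.8 against 540.2 ± 44.5 TPM and Eng, a co-receptor for BMP ligands, at 370.6 ± 75.7 against 636.6 ± 87.6 TPM (SD, n = 3). The list median was -0.043 with median-of-ratios scaling and 0.0043 with the correction for GC content and length. Arterial markers (adjusted p = 0.43) had a median of 0.034, a mean of -0.14 and a camera direction of higher. Lymphatic markers (adjusted p = 0.24) had a median of -0.48 over the 6 tested of 10 listed genes, with Lyve1 at 640.1 ± 72.5 against 977.9 ± 134.6 TPM and Ccl21a lower adjusted over the list alone. The lymphatic genes Prox1 and Reln were too low to test, at 0.031 against 0.085 TPM and 0.014 against 0.027 TPM. Whether the Lyve1 values come from lymphatic cells was not tested. Basement membrane and extracellular matrix genes (adjusted p = 0.062) had 8 of 19 genes lower and 1 higher, Sparc, adjusted over the list alone. Among the lower ones was Bgn at 85.2 ± 16.4 against 184.6 ± 56.3 TPM. The senescence and secretory list (adjusted p = 0.12) had 4 of 24 genes lower, among them the cell cycle inhibitor gene Cdkn2b at 24.6 ± 3.64 against 47.0 ± 11.5 TPM and Igfbp5 at 4.02 ± 1.45 against 12.6 ± 3.09 TPM. Imprinted genes (adjusted p = 0.49) had 1 higher and 4 lower, with Igf2 at 4.50 ± 0.712 against 1.61 ± 0.369 TPM and Mest at 10.9 ± 2.13 against 23.7 ± 5.87 TPM. Hox and developmental patterning genes (adjusted p = 0.064) had 3 lower, VEGF signalling (0.44) 1 higher and 3 lower, antioxidant genes (0.69) 2 lower and TGF-beta and BMP signalling (0.11) 1 lower, each adjusted over the list alone.

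The other lists that did not pass were enhancer and chromatin regulators (camera adjusted p = 0.97), endothelial inflammation (0.69, with Cx3cl1 lower adjusted over the list alone), nuclear-encoded oxidative phosphorylation (0.83), cytosolic ribosomal proteins (0.49, with Rps19 higher adjusted over the list alone), Notch signalling (0.69), shear stress genes (0.49), coagulation (0.42), lipid handling (0.44), protein folding stress (0.69, with Calr higher adjusted over the list alone), immediate early genes of cell dissociation (0.44), the circadian clock (0.44) and clustered protocadherins (0.44). Of the lists too small to test, 0 genes of the methylation-silenced germline list reached a mean of 1 TPM, 0 mitochondrially encoded genes were in the table, and neutrophil markers and sex-linked transcripts had 3 and 2 tested genes.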

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

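The tests with GC content and length, protein-coding genes alone and small RNA genes removed were chosen after the data were seen. The number of genes past limma's adjusted threshold was 3, and it was 0 with no filter, 16 with quantile normalization, 94 with library weights, 28 among protein-coding genes, 25 with small RNA genes removed and between 0 and 2 without 1 library. The number of genes tested was 19206 with no filter, 11682 among protein-coding genes and 12772 with small RNA genes removed, against 12748. With protein-coding genes alone no rescaling was done, so the values of each kept gene stayed the same. That count can differ only through the variance estimate shared across genes and the number of tests. The cause was not tested for the other settings. At an unadjusted p under 0.05 there were 1714 genes, 2584 with library weights and between 1135 and 2112 without 1 library. The number of lists past the camera threshold was 12, between 13 and 15 without 1 library, 0 with an estimated correlation and 0 by fry's test for movement one way. Members past the threshold adjusted over the list alone numbered 77, 123 with library weights and between 50 and 100 without 1 library. In 1276 alternatives of 65 named genes, 1178 stayed on their side of the threshold in the same direction, 31 lost and 61 gained it. Only 3 of these genes had passed, so most of the 1178 are genes that stayed short of the threshold. Of the 3, Gm7609 passed in 10 of 19 alternatives, Lmbr1 in 11 of 20 and Frrs1 in 7 of 20. The changes of direction were in genes and a list that had not passed. Without 1 library the log2 difference of Dnmt1 lay between -0.243 and 0.019 and that of Tet1 between -0.247 and 0.032, and the cause was not tested. Dnmt1 was at 0.074 with the GC and length correction, with or without the block. Scgb1a1 was at -0.010 with library weights, and the DNA methylation machinery was tested as lower with a mean of at least 5 TPM (median -0.13) and by fry (median -0.12).

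The labels do not say whether equal replicate numbers pair the libraries. Deviations from the group means correlated at -0.012, -0.090 and 0.057 between libraries of the same number. These correlations are over all genes, so they cannot exclude a pairing that acts on some genes. The replicate block gave 0 genes (1445 at an unadjusted p under 0.05) and, with the GC and length correction, 0 genes (1426) and 42 members adjusted over the list alone. With the block 12 lists passed. Rescaling to the same sum moved each library by nearly the same factor, since no mitochondrial or ribosomal RNA gene is in the table. The depth is unknown, so what it limits cannot be given. In simulated values the limma test called 35 of 50 genes changed by 1 on the log2 scale and 9 of 50 changed by 0.5. Those shares hold for many genes changed at once, all with a mean of at least 5 TPM. They are likely too high for a comparison with few calls.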

Other observations

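The gene families in this paragraph were chosen after the data were seen, and camera's adjusted p over 8 such families lay at 0.18 or above for each with an estimated correlation. All 10 tested guanylate-binding protein genes, which interferon gamma induces, were higher at 18 months, with a median log2 difference of 0.77 (camera adjusted p = 2.5e-10), and 0.45 without the second 18-month library. All 6 tested Oas genes were higher, with a median of 0.45 (camera adjusted p = 6.6e-07), and 0.31 without that library. All 12 tested collagen genes were lower, with a median of -0.57 (camera adjusted p = 3.3e-06), and -0.37 without the second 8-month library. Markers of fibroblasts (median -0.51) and of smooth muscle and pericytes (median -0.67) were lower too, and the collagens were not tested apart from them. Genes of motile cilia had a median of 0.087 over 35 genes, 23 of them higher (camera adjusted p = 1.1e-05). Airway epithelium markers were higher too (median 0.55), and the cilium genes were not tested apart from them. The cilium median was 0.14 without the third 18-month or the third 8-month library, 0.15 without the second 8-month library, 0.17 with median-of-ratios scaling, 0.14 with quantile normalization and 0.18 with a correction for GC content and length. Box C/D snoRNA genes had a median of 0.55 over 39 genes (camera adjusted p = 3.4e-09), 0.32 without the first 18-month library, and 0.26 after that correction. MicroRNA genes had a median of 0.32 over 247 genes (camera adjusted p = 7.8e-09), which was 0.050 without the first and 0.59 without the third 18-month library. It was 0.20, 0.50 and 0.20 without the first, the second and the third 8-month library, and 0.082 after that correction. Reads of 100 bp are longer than a microRNA gene such as Mir7663, and whether these values measure microRNAs was not tested. Ribosomal protein genes (camera adjusted p = 0.48) and proteasome subunits (0.19) did not pass. The directions of the first 4 families were the same with median-of-ratios scaling and quantile normalization.

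The loci in this paragraph were also chosen after their values were seen. Frrs1 fell, while its neighbour Palmd (chromosome 3, 116918258 to 116968987, GRCm38) lay at 241.9 TPM at 18 months against 143.1 TPM at 8 months, a log2 difference of 0.75 that did not pass (limma adjusted p = 0.086). On chromosome 4, the copies Gm13304, Gm21541 and Gm10591 have identical values, listed at 0 in the 18-month libraries and at 1.86, 4.13 and 3.97 TPM in the 8-month libraries (limma adjusted p = 0.077). The nearby chemokine gene Ccl21a lay at 1.57 against 14.5 TPM (limma adjusted p = 0.16), and its copy Ccl21b at 0.511 to 1.09 TPM in the 18-month libraries and near 0 at 8 months. The identical values give no separate measure of the 3 copies, and sequence shared with Ccl21a and Ccl21b was not tested. Mir6236 had 55989, 41621 and 40438 TPM at 18 months and 24746, 27002 and 35236 TPM at 8 months. Whether these values measure a microRNA was not tested.

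The tests in the next paragraphs were chosen after the results were seen. Each compares a number with one it would have under a technical explanation, and age itself stays among the open explanations as untested.

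MHC class II genes were higher at 18 months. B cells and alveolar epithelial cells carried over in the sort are argued against by their own markers: in mean log2(TPM + 0.1) per library the MHC class II list rose over the B cell list by 1.71 with an SE of 0.60 and over the alveolar list by 1.59 with an SE of 0.48, and the ages did not overlap in either. A trend with GC content and length is also argued against as the whole cause, since the median of the list was 1.41 after that correction against 1.28 before it (camera adjusted p = 3.1e-08 after it, and adjusted p = 0.50 with an estimated correlation before it), while the median of all genes moved by 0.092. Carried-over monocytes, macrophages or dendritic cells cannot be told apart from a rise within endothelial cells: over their markers, which share no gene with the list, the MHC class II genes rose by 0.55 with an SE of 0.49, and the markers themselves by 0.76 with an SE of 0.57. The most abundant of these were Lyz2 and Chil3. Their means were 1046 and 260.0 TPM at 18 months and 909.7 and 66.1 TPM at 8 months. Among the 8-month libraries both were highest in the third, with Chil3 at 26.7, 31.4 and 140.1 TPM. How well the sort removed such cells is not known. RNA of other cells was present, with the club cell gene Scgb1a1 at 9171 TPM at 18 months and 6312 TPM at 8 months.

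Cell cycle genes were higher at 18 months. After the correction for GC content and length the list median was 0.48 against 0.37 before it (camera adjusted p = 5.1e-12 after it, and adjusted p = 0.50 with an estimated correlation before it), with the same move of 0.092 in all genes, which argues against that trend as the whole cause. Dividing macrophages cannot be told apart from dividing endothelial cells, since the cell cycle list rose over the macrophage markers by 0.086 with an SE of 0.56.

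Of the genes at an unadjusted p under 0.05, 74.3% were lower at 18 months. This share was 54.7% with median-of-ratios scaling, but that scaling brings the median of all genes close to 0 by its construction, so scaling of the libraries cannot be told apart from a real excess. Small RNA genes, which took 49183 to 74058 TPM at 18 months and 32736 to 43808 TPM at 8 months, could account for part of it, with a share of 66.6% once they were removed, which leaves their role open. The excess went with GC content: with median-of-ratios scaling 35.7% were lower in the fifth of genes with the lowest GC content and 81.9% in the fifth with the highest, a gap of 46.2 points. With the GC and length correction the share was 46.9%, so the direction turned, but that correction also brings the median of all genes close to 0, and whether the GC trend reflects library preparation or the genes that age moves was not tested.

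The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the adjusted threshold 1 split, the ages themselves, gave as many (3 genes, highest other 2), for genes at an unadjusted p under 0.05 also 1, the ages themselves (1714, highest other 1073), and for lists past the camera threshold 5, the ages included (12 lists, highest other 15).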
